A study of Mus musculus with 6 samples.

How the data were processed

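The libraries came from oligo(dT)-purified messenger RNA of mouse skin and were read as single-end fragments on DNA nanoballs, per the labels' protocols. Reads were aligned with HISAT (version not given), per the submitters' processing notes; the counter, genome build and annotation are not given in the sources used here, so no coordinates are printed. The deposited table holds FPKM per gene and library, per the file headers, a measure scaled to gene length and to mapped fragments per library, rounded to 2 decimals and keyed by NCBI Gene ID. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical. The count of reads behind a value could not be recovered from the steps between low values, so depth is unknown.

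Of 18939 genes, 356 were listed at 0 in all 6 libraries. The gene IDs were looked up in a RefSeq table of assembly GRCm38.p6, used for names only, and 18881 were found; 24 symbols deposited as dates were resolved in this way. Genes with at least 1 FPKM in at least 3 libraries were tested (12994), and 5945 were not. The design fixed before the data were examined named a count test with a limma test for normalized values in its place; as the table holds FPKM, the limma test was used.

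Differences (CKO minus FLOX) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step and no other covariate. The tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Means and SDs are of FPKM over 3 libraries. Gene lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera's estimated correlation and fry beside it. The 44 lists, of which 41 could be tested, were written from general knowledge of skin and allergic inflammation before the data were examined and hold markers of the other cell types a skin sample can contain. Some genes stand in several lists, and skin cells other than those a list is named for express some of its members.

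Named genes followed a rule set in advance. It took Vamp7 and 20 fixed genes of basophils, type 2 inflammation and epidermis. It also took up to 10 genes per direction with the largest fold change among those past the threshold, with groups apart and a group mean of at least 5 FPKM, leaving out provisional gene names. Of each list past camera it took the 2 members with the smallest p and the 2 with the highest mean. Some genes that the rule takes are not reported here.

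The test was checked on simulated data for the CKO and FLOX comparison, with 12994 genes, 200 of them changed, in 5 runs. It recovered 94.5% of genes changed 2-fold and 99.8% of those changed 4-fold, with 6.93% false calls. A shifted list was called in 5 of 5 runs and 1.08% of other lists were called. The simulated genes varied independently, while genes of many lists here were correlated (estimated correlation 0.929 for the skeletal muscle list). The list check therefore does not measure camera's false calls in these data. The noise was also normal, with each gene's spread drawn toward that of other genes. The recovery of changed genes therefore need not hold in these data. Il4 (log2 fold change -2.26) and Osm (-2.14), for example, did not pass.

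Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, empirical Bayes without trend or with robust fitting, array weights, the replicate number as a block, tested genes without those of muscle, fat, hair, cartilage and blood lists, and leaving out each library. For the fit without genes of other tissues, the remaining values of each library were also rescaled to a common sum. A fit with the skeletal muscle list's mean per library as a covariate was added after seeing the data. Alternatives that need read counts were left out.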

Results

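Messenger RNA of mouse skin was sequenced in 6 libraries, 3 labelled CKO (replicates 1, 2 and 5), from mice lacking VAMP7 in basophils, and 3 titled FLOX (replicates 2, 3 and 5), with a wild-type genotype label. VAMP7 is a vesicle SNARE, a protein that drives membrane fusion. Basophils are rare granulocytes that release histamine and interleukin 4. The series title names an MC903-OVA model. MC903 is calcipotriol, a vitamin D analogue that causes inflammation resembling atopic dermatitis when put on mouse skin, and ovalbumin is a model antigen. The comparison asks how the inflamed skin differs when basophils lack VAMP7. Untreated skin was not analysed here. The deposited FPKM values cover 18939 genes, and their sums per library ran from 556412 to 594987. Read depth per library is unknown, so no counting interval or detection floor is given. Correlations of log2(FPKM + 1) across genes were 0.986 to 0.989 between CKO libraries, 0.989 to 0.992 between FLOX libraries and 0.966 to 0.988 across the groups. The first principal component held 56.4% of the variance and placed the CKO libraries at 14.9, 31.07 and 6.03 and the FLOX libraries at -17.66, -15.46 and -18.88.

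Vamp7 (NCBI Gene ID 20955), the targeted gene, measured 19.5 ± 0.352 FPKM in CKO skin and 20.9 ± 0.565 FPKM in FLOX skin (mean ± SD, n = 3 each). The CKO values were 19.71, 19.11 and 19.73 FPKM and the FLOX values 20.4, 21.51 and 20.77 FPKM, so the groups did not overlap, and the CKO mean was 6.59% lower. The difference did not pass the test across genes (log2 fold change -0.09, SE 0.07, limma adjusted p = 0.475). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. Groups did not overlap for 26.95% of tested genes, so neither the separation nor this p marks Vamp7 out. The deletion was made in basophils and the tissue was skin, in which other cells also express Vamp7, so this level checks the labels only weakly.

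CKO skin had 46 genes higher and 78 genes lower than FLOX skin among 12994 tested (limma with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 the balance was the other way, with 1641 higher and 1162 lower. That balance depended on the scaling of the libraries. Median-ratio scaling gave 1305 higher and 1498 lower at the same unadjusted limit, and quantile normalization 1286 and 1346. The falls given next are the 10 largest among genes past the threshold with a group mean of at least 5 FPKM, leaving out genes known only by a provisional Gm symbol. Mcpt8 (NCBI Gene ID 17231), a protease restricted to basophils, measured 20.8 ± 6.63 FPKM in CKO and 98.9 ± 18.1 FPKM in FLOX skin, a 4.75-fold difference of means. Values here and below are means ± SD of 3 libraries, with CKO given first where the groups are not named. Il1b, which encodes interleukin 1 beta, was 84.9 ± 30.5 against 359 ± 148 FPKM. Retnlg, a resistin-like gene of neutrophils, was 47.8 ± 21.0 against 183 ± 29.6 FPKM. The other 7 of these genes were Cd14, a co-receptor for bacterial lipopolysaccharide (log2 fold change -1.48, SE 0.25), Mmp8, the neutrophil collagenase (-1.38, SE 0.21), and Clec4d, a myeloid C-type lectin (-1.37, SE 0.23). They also included the growth factor gene Pgf (-1.37, SE 0.15), Spatc1 (-1.37, SE 0.20), the natriuretic peptide gene Nppb (-1.33, SE 0.21) and the formyl peptide receptor gene Fpr2 (-1.32, SE 0.21).

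Among genes past the threshold with a group mean of at least 5 FPKM, the 10 with the largest rises follow. Flg2, which encodes a filaggrin-like protein of the cornified layer, rose from 4.53 ± 1.6 to 13.8 ± 0.825 FPKM, and Lce1m, a late cornified envelope gene, from 8 ± 2.23 to 22.5 ± 4.10 FPKM. Skint9, of a family expressed in skin and thymus epithelium, rose from 13.3 ± 0.423 to 34.6 ± 5.03 FPKM and had the smallest unadjusted p in the table (4.15e-06). Ear2, an eosinophil-associated ribonuclease gene, rose from 13.9 ± 3.56 to 37.5 ± 1.61 FPKM. Mup19, a major urinary protein gene, had the largest log2 fold change of the 10 (2.54, SE 0.37), followed by Nnat, an imprinted gene (1.70, SE 0.27). Myh2, a myosin of fast skeletal muscle fibres (1.48, SE 0.17), and Jsrp1, a sarcoplasmic reticulum gene (1.37, SE 0.23), were also among the 10, as were Slurp2 (1.37, SE 0.18) and the carboxylesterase gene Ces1d (1.30, SE 0.19). Mup19, Ear2, Lce1m and Skint9 belong to families of close copies, and their values are uncertain because reads can be shared between the copies.

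The called genes stood close to the threshold. Of the 124, 120 shared the smallest adjusted p of 0.047 and the largest was 0.0489. In all 124 the 3 CKO values lay on one side of the 3 FLOX values. Calling genes by a small p favours such separation, so it adds no support. It held for 26.95% of tested genes, against 10% expected by chance. Genes varied together, so this share can lie far from 10% without a group effect. After median-ratio scaling the counts were 42 higher and 116 lower. The call counts depended on single libraries. Without FLOX replicate 2 or FLOX replicate 3, limma called 0 genes, with 1119 higher and 878 lower, and 1436 higher and 963 lower, at an unadjusted p under 0.05. Without FLOX replicate 5 it called 2 higher and 1 lower, without CKO replicate 2 it called 1 higher and 6 lower, and without CKO replicate 5 it called 225 higher and 192 lower. Without CKO replicate 1 it called 69 higher and 65 lower.

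**Figure D1:**
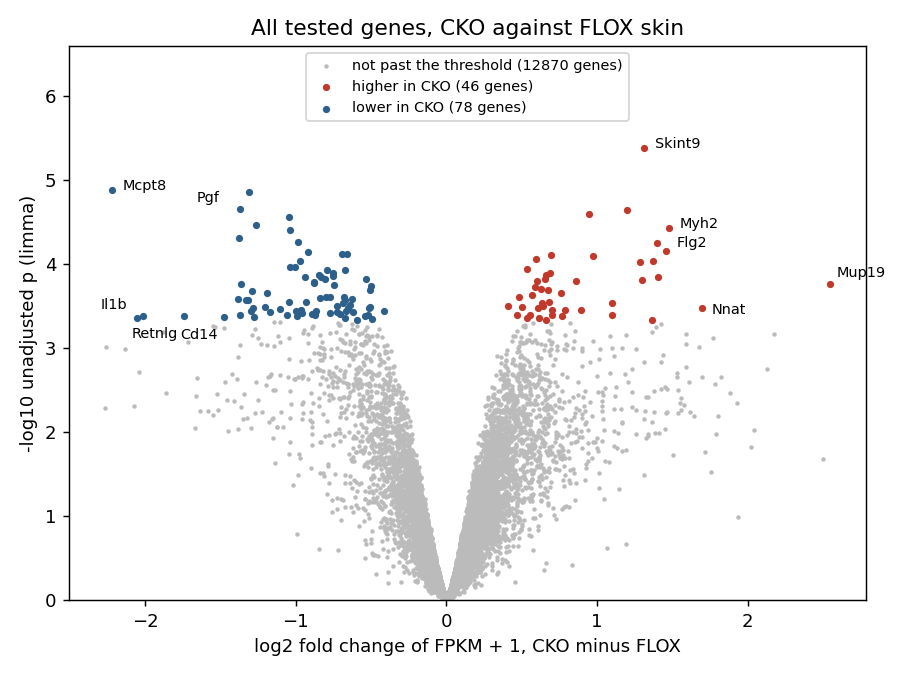
Each point is 1 of 12994 tested genes, with the log2 fold change of FPKM + 1 (CKO minus FLOX) on the horizontal axis and minus log10 of the unadjusted limma p on the vertical axis. The 46 genes higher in CKO are red and the 78 lower are blue, with Mcpt8 at -2.22 and Mup19 at 2.54.

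Basophil genes were lower in CKO skin. Of 11 tested members of the basophil list, 9 had negative fold changes and 2 fell, Mcpt8 (log2 fold change -2.22, SE 0.22) and Prss34, another basophil protease (-0.92, SE 0.12). The other 9 did not pass; adjusted over the list alone, 6 were lower. The list's median was -0.54 (camera adjusted p = 4.20e-06; adjusted p = 0.341 with an estimated correlation). Il4, the type 2 cytokine of basophils and T cells, measured 16.9 ± 12.7 FPKM in CKO and 76.0 ± 42.6 FPKM in FLOX skin and did not pass (adjusted p = 0.0825). Cd200r3, an activating receptor of basophils and mast cells, measured 6.11 ± 0.898 and 9.88 ± 1.16 FPKM (adjusted p = 0.0567). The skeletal muscle list, by contrast, was higher by a median of 1.46 in the same CKO libraries. With the mean of that list as a covariate the basophil list still passed camera in the same direction.

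The mast cell list ranked higher in CKO skin. None of its 13 tested members passed over all genes, 4 were higher and 1 lower adjusted over the list alone, and the median was 0.33 (camera adjusted p = 0.0261; adjusted p = 0.365 with an estimated correlation). Mcpt4, a protease of connective tissue mast cells, measured 197 ± 7.50 FPKM in CKO and 177 ± 19.8 FPKM in FLOX skin. Cpa3, carboxypeptidase A3 of mast cells and basophils, measured 186 ± 6.76 and 175 ± 8.78 FPKM, and the receptor gene Mrgprb1 8.73 ± 0.651 and 5.82 ± 0.576 FPKM. Hdc, which makes histamine and is also used by basophils and neutrophils, had the opposite sign, with 83.7 ± 15.5 and 189 ± 51.0 FPKM (adjusted p = 0.0515). Without FLOX replicate 3 the mast cell list did not pass (camera adjusted p = 0.111), nor with the filter at 5 FPKM (0.0665), and its median was 0.20 without that library. The muscle list was higher by a median of 1.46 in the same CKO libraries, and with its mean as a covariate the mast cell list did not pass (0.17). For every list here, that fit separates muscle content from genotype only weakly, whether the list then passes or not. The muscle list's means did not overlap between the groups, and 3 residual degrees of freedom remained.

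Neutrophil genes were lower in CKO skin. All 13 tested members of the list had lower means, 6 fell, and 12 were lower adjusted over the list alone, with a median log2 fold change of -1.19 (camera adjusted p = 6.47e-13; adjusted p = 0.341 with an estimated correlation). Besides Retnlg, Mmp8 and Il1b, these were the chemokine receptor gene Cxcr2 (27.8 ± 6.93 against 63.9 ± 7.99 FPKM), Ly6g (0.54 ± 0.03 against 2.12 ± 0.539 FPKM) and S100a9 (1148 ± 156 against 2310 ± 405 FPKM). S100a9 encodes a subunit of calprotectin. Its partner S100a8 measured 1622 ± 291 and 2917 ± 593 FPKM and did not pass (adjusted p = 0.0667). Both genes also stand in the hyperproliferative epidermis list, so their values are not specific to neutrophils. In the same libraries the skeletal muscle list was higher in CKO by a median of 1.46. The neutrophil list still passed camera in the same direction with that list's mean as a covariate.

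General leukocyte genes and macrophage genes were also lower. Of 15 leukocyte genes, 2 fell, the tetraspanin gene Cd53 (118.8 ± 17.1 against 218.8 ± 23.2 FPKM) and the signalling gene Vav1 (12.5 ± 0.443 against 18.6 ± 0.996 FPKM). The other 13 did not pass, among them the signalling adaptors Tyrobp (429 ± 97.2 against 664 ± 40.7 FPKM) and Fcer1g (270.4 ± 57.1 against 370.8 ± 34.1 FPKM). Adjusted over the list alone 14 were lower, and the median was -0.51 (camera adjusted p = 3.49e-12; adjusted p = 0.341 with an estimated correlation). Of 16 monocyte and macrophage genes, Cd14 fell and 15 did not pass, 9 were lower adjusted over the list alone, and the median was -0.34 (camera adjusted p = 1.89e-07; adjusted p = 0.341 with an estimated correlation). Mrc1, the mannose receptor, measured 171 ± 9.93 and 257 ± 29.8 FPKM, the complement gene C1qb 519 ± 59.2 and 615 ± 35.3 FPKM, and the lysozyme gene Lyz2 1613 ± 166 and 1712 ± 263 FPKM. The skeletal muscle list was higher by a median of 1.46 in the same libraries. With its mean as a covariate the leukocyte and the monocyte and macrophage lists still passed camera in the same direction.

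Eosinophil genes split. Ear2 rose, and the other 7 tested members did not pass; adjusted over the list alone 1 was higher and 4 were lower, and the median was -0.45 (camera adjusted p = 0.0389; adjusted p = 0.551 with an estimated correlation). Siglecf, a surface lectin of eosinophils, measured 3.37 ± 0.793 FPKM in CKO and 5.86 ± 1.44 FPKM in FLOX skin. The eotaxin receptor gene Ccr3 measured 3.36 ± 0.722 and 7.33 ± 2.61 FPKM, and Prg2, the major basic protein gene, 10.1 ± 2.36 and 20.4 ± 8.31 FPKM. The list did not pass without CKO replicate 1 (camera adjusted p = 0.0509), CKO replicate 2 (0.091), FLOX replicate 2 (0.128) or FLOX replicate 3 (0.083), nor with the filter at 5 FPKM (0.619) or median-ratio scaling (0.0793). Its median was -0.26 without CKO replicate 2. The muscle list was higher by a median of 1.46 in these CKO libraries, and with its mean as a covariate the eosinophil list did not pass (0.0633).

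**Figure D2:**
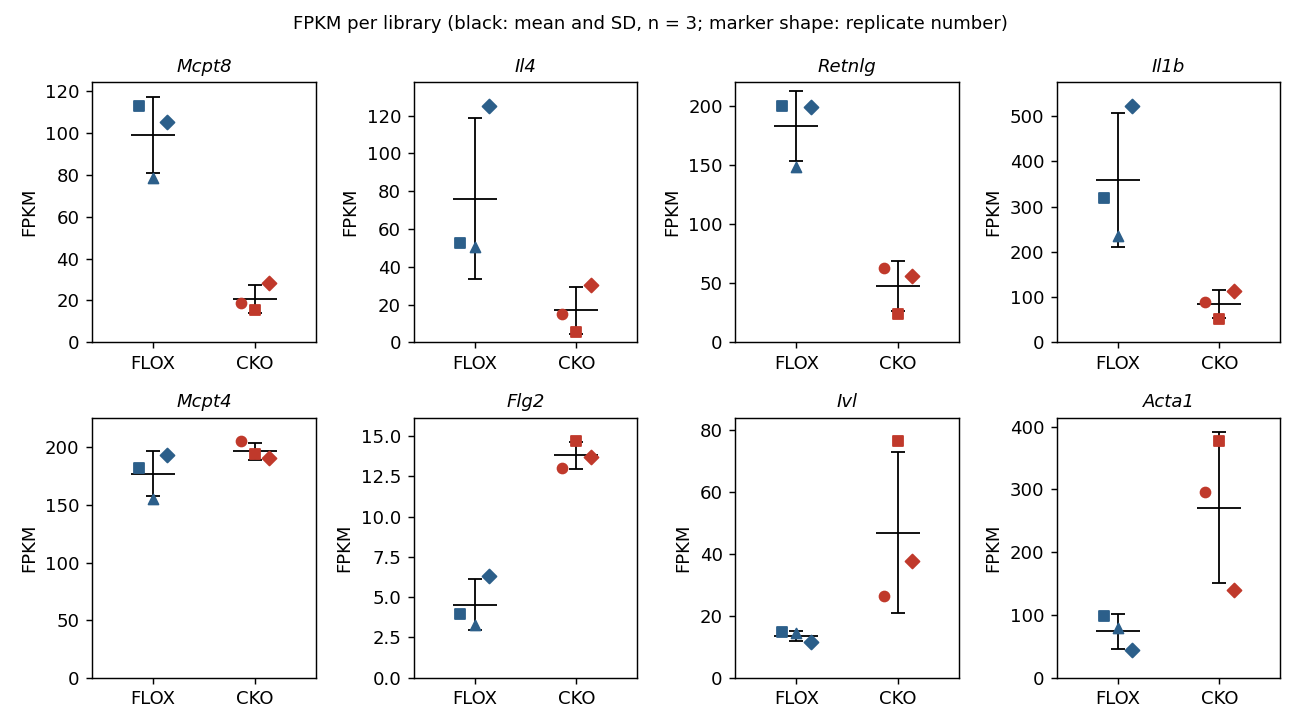
FPKM of 8 genes in each of the 6 libraries, with the mean and SD of each group in black and the replicate number as the marker shape. Mcpt8 lies between 15.32 and 28.19 FPKM in CKO and between 78.48 and 112.91 FPKM in FLOX libraries, and Flg2 between 13.03 and 14.67 FPKM in CKO and between 3.3 and 6.34 FPKM in FLOX libraries.

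Most type 2 cytokine genes had lower means in CKO skin, with wide spread between libraries. Of the 10 tested members 8 had negative fold changes, none passed over all genes, 4 were lower adjusted over the list alone, and the median was -0.46 (camera adjusted p = 0.0151; adjusted p = 0.393 with an estimated correlation). Besides Il4, the eosinophil chemoattractant gene Ccl24 measured 55.3 ± 30.9 FPKM in CKO and 217 ± 92.5 FPKM in FLOX skin, and Ccl8, a monocyte and T cell chemoattractant gene, 2610 ± 586 and 3843 ± 559 FPKM. Il13 measured 2.87 ± 1.78 and 7.14 ± 2.23 FPKM, and Ccl11 52.5 ± 12.4 and 74.2 ± 29.4 FPKM. The epithelial alarmin genes Tslp (78.2 ± 35.9 and 104.9 ± 31.0 FPKM) and Il33 (119.7 ± 32.4 and 152 ± 26.1 FPKM) did not pass either (adjusted p = 0.474 and 0.361). Il5 averaged 0.157 and 0.15 FPKM and Il31 0.107 and 0.23 FPKM, below the filter for testing. The list did not pass without CKO replicate 1 (camera adjusted p = 0.103) or FLOX replicate 2 (0.0885), nor with the filter at 5 FPKM (0.0762). In the same libraries the skeletal muscle list was higher in CKO by a median of 1.46, and the type 2 cytokine list did not pass with the mean of that list as a covariate (0.718).

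Genes of type 2 receptors and of other inflammatory signals ranked lower as well. Of 15 receptor and signalling genes none passed over all genes; adjusted over the list alone 1 was higher and 5 were lower, with a median of -0.26 (camera adjusted p = 0.000933; adjusted p = 0.341 with an estimated correlation). Il4ra, the shared receptor chain of interleukins 4 and 13, measured 129.4 ± 26.0 and 218.6 ± 36.9 FPKM, Il13ra2, the decoy receptor for interleukin 13, 10.8 ± 2.40 and 16.3 ± 0.127 FPKM, and the feedback inhibitor gene Socs3 102.6 ± 27.7 and 200.3 ± 61.4 FPKM. Of 10 type 1 and type 17 genes, Il1b fell and 9 did not pass, 4 were lower adjusted over the list alone, and the median was -0.65 (camera adjusted p = 0.000280; adjusted p = 0.365 with an estimated correlation). Il6 measured 21.9 ± 13.6 and 88.4 ± 39.8 FPKM and the neutrophil chemokine gene Cxcl5 60.7 ± 29.8 and 177.8 ± 59.6 FPKM. Of 13 itch genes, Nppb fell and 12 did not pass, 1 was higher and 5 were lower adjusted over the list alone, and the median was -0.33 (camera adjusted p = 0.0115; adjusted p = 0.341 with an estimated correlation). Osm, the oncostatin M gene, measured 18.8 ± 10.4 and 85.1 ± 42.4 FPKM (adjusted p = 0.0521). None of the 14 immediate early genes passed over all genes; 7 were lower adjusted over the list alone, with a median of -0.49 (camera adjusted p = 6.14e-06; adjusted p = 0.341 with an estimated correlation). Among them Ier3 measured 95.2 ± 30.8 and 227 ± 43.8 FPKM and Junb 164.9 ± 22.0 and 265 ± 45.5 FPKM. In these libraries the skeletal muscle list was higher in CKO by a median of 1.46. With that list's mean as a covariate the type 2 receptor list (camera adjusted p = 0.12), the type 1 and type 17 list (0.394) and the itch list (0.153) did not pass. The median of the type 1 and type 17 list was -1.01 without FLOX replicate 3, and that of the itch list was -0.60 without CKO replicate 1 and -0.14 without CKO replicate 2.

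Genes of the differentiated epidermis were higher in CKO skin. Of 27 tested, 24 had positive fold changes, Flg2 and Lce1m rose and 25 did not pass; 10 were higher adjusted over the list alone, and the median log2 fold change was 0.38 (camera adjusted p = 3.90e-06; adjusted p = 0.393 with an estimated correlation). Flg, the filaggrin gene, measured 69.6 ± 25.2 FPKM in CKO and 35.4 ± 9.08 FPKM in FLOX skin (adjusted p = 0.093), and the involucrin gene Ivl 46.9 ± 26.1 and 13.6 ± 1.67 FPKM (adjusted p = 0.0619). The abundant members Krtdap (2923 ± 280 and 2398 ± 205 FPKM) and Calm4 (2643 ± 570 and 1906 ± 195 FPKM) did not pass. Basal keratinocyte genes ranked higher as well. None of 10 passed over all genes, 3 were higher adjusted over the list alone, and the median was 0.23 (camera adjusted p = 0.00691; adjusted p = 0.365 with an estimated correlation). Krt15 measured 74.2 ± 18.5 and 43.5 ± 4.40 FPKM, Trp63, the p63 transcription factor gene, 44.1 ± 5.18 and 32.7 ± 1.99 FPKM, Krt14 3946 ± 180 and 3583 ± 230 FPKM, and Krt5 1124 ± 191 and 828 ± 158 FPKM. Keratins of hyperproliferative epidermis differed little, with Krt6a at 1345 ± 203 and 1446 ± 49.7 FPKM and Krt16 at 2025 ± 340 and 1878 ± 130 FPKM. Of the 19 tested genes of their list 1 fell, S100a9, 2 were lower adjusted over the list alone, and the median was -0.06 (camera adjusted p = 0.129), from -0.17 without CKO replicate 5 to 0.01 without CKO replicate 1. The skeletal muscle list was higher by a median of 1.46 in the same CKO libraries. With its mean as a covariate the differentiated epidermis list still passed camera in the same direction. The basal keratinocyte list did not pass in that fit (camera adjusted p = 0.227).

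Most lipid genes of the skin had higher means in CKO skin, without a member past the test over all genes. The 17 epidermal lipid barrier genes had a median of 0.42, with 7 higher adjusted over the list alone (camera adjusted p = 0.000318; adjusted p = 0.390 with an estimated correlation). Sptlc3, a subunit of the enzyme that starts sphingolipid synthesis, measured 16.2 ± 2.19 and 9.02 ± 1.65 FPKM, the sphingomyelinase gene Smpd1 34.9 ± 2.46 and 26.7 ± 1.44 FPKM, and the fatty acid elongase genes Elovl4 238 ± 31.9 and 156.8 ± 41.0 FPKM and Elovl1 91.4 ± 14.4 and 77.7 ± 4.13 FPKM. The 15 sebaceous gland genes had a median of 0.54, with 3 higher adjusted over the list alone (camera adjusted p = 0.000318; adjusted p = 0.393 with an estimated correlation). Krt79 measured 131.7 ± 20.0 and 71.6 ± 22.3 FPKM, the fatty acid synthase gene Fasn 16.9 ± 3.32 and 10.7 ± 1.39 FPKM, the desaturase gene Scd1 464 ± 100.7 and 317 ± 62.2 FPKM, and Mgst1 178 ± 18.5 and 150.3 ± 16.7 FPKM. All 18 cholesterol synthesis genes had positive fold changes with a median of 0.25, and 3 were higher adjusted over the list alone (camera adjusted p = 0.000306; adjusted p = 0.390 with an estimated correlation). Dhcr7 measured 25.3 ± 0.325 and 17.9 ± 2.08 FPKM, Hmgcs1 72.1 ± 1.54 and 57.0 ± 1.51 FPKM, and Msmo1 135.8 ± 12.6 and 112.6 ± 11.5 FPKM. The 13 tight junction and epidermal protease genes had a median of 0.26 with 0 past the limma test over all genes or adjusted over the list alone (camera adjusted p = 0.0176; adjusted p = 0.390 with an estimated correlation). Klk5 measured 40.1 ± 5.86 and 25.0 ± 4.88 FPKM, Prss8 16.1 ± 1.49 and 12.5 ± 1.09 FPKM, Klk7 505 ± 72.0 and 468 ± 71.1 FPKM, and Klk8 124.7 ± 16.2 and 118.3 ± 32.7 FPKM. That list did not pass without CKO replicate 5 (camera adjusted p = 0.0859) or FLOX replicate 3 (0.0937), and its median was 0.39 without CKO replicate 1. The median of the lipid barrier list was 0.26 without CKO replicate 2 and that of the sebaceous list 0.33 without FLOX replicate 3. The skeletal muscle list was higher by a median of 1.46 in these CKO libraries, and the adipocyte list by 0.88, with overlap between the groups.

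Skeletal muscle genes were higher in CKO skin, and fat genes ranked higher with overlap between the groups. All 23 tested muscle genes had positive fold changes, Myh2 rose, 22 did not pass, and 23 were higher adjusted over the list alone, with a median of 1.46 (camera adjusted p = 1.18e-12; adjusted p = 0.390 with an estimated correlation). Acta1, skeletal muscle actin, measured 271 ± 120.1 FPKM in CKO and 73.6 ± 27.2 FPKM in FLOX skin, and Mylpf, a fast myosin light chain gene, 245 ± 106 and 91.1 ± 31.1 FPKM. The mean of the list relative to FLOX was 1.58, 2.08 and 0.79 in CKO replicates 1, 2 and 5 and 0.45, 0.19 and -0.64 in FLOX replicates 2, 3 and 5. The 13 adipocyte genes had a median of 0.88 with none past the test over all genes and 5 higher adjusted over the list alone (camera adjusted p = 6.30e-05; adjusted p = 0.393 with an estimated correlation). The resistin gene Retn measured 32.5 ± 12.5 and 13.9 ± 2.76 FPKM, the perilipin gene Plin4 14.4 ± 4.18 and 7.20 ± 1.68 FPKM, Fabp4 459 ± 207 and 296 ± 121 FPKM, and Car3 148 ± 69.7 and 75.2 ± 27.5 FPKM. The mean of the adipocyte list relative to FLOX was 1.51, 0.86 and 0.28 in CKO replicates 1, 2 and 5 and -0.09, -0.29 and 0.38 in FLOX replicates 2, 3 and 5, so the groups overlapped, and its median was 0.58 without CKO replicate 1. With the muscle list's mean as a covariate, an alternative chosen after seeing the data, limma called 0 genes (388 higher and 240 lower at an unadjusted p under 0.05). Camera then passed 17 lists, among them the red blood cell list (camera adjusted p = 2.4e-05) and the alternatively activated macrophage list (0.0223), which had not passed without the covariate. The type 2 cytokine, type 2 receptor, type 1 and type 17, itch, mast cell, eosinophil, adhesion, endothelial, cell cycle, basal keratinocyte and smooth muscle lists and the skeletal muscle list itself (camera adjusted p = 0.789) no longer passed. For the skeletal muscle list this was fixed in advance, because the covariate is its own mean. All other lists past camera without the covariate still passed with it, in the same direction. Among them were the neutrophil, basophil, leukocyte, macrophage, immediate early and differentiated epidermis lists. The lipid barrier, tight junction, sebaceous, cholesterol, adipocyte, nerve, cartilage, SNARE and unfolded protein lists were the rest.

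Most nerve, smooth muscle and cartilage genes also had higher means. Of 10 nerve and Schwann cell genes 1 rose and 9 did not pass; 7 were higher adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.000236; adjusted p = 0.393 with an estimated correlation). Pmp22, a myelin gene (122 ± 9.47 and 110.5 ± 7.59 FPKM), and S100b (42.6 ± 8.22 and 31.3 ± 5.22 FPKM) did not pass. None of 9 smooth muscle and pericyte genes passed over all genes, 6 were higher adjusted over the list alone, and the median was 0.53 (camera adjusted p = 0.000793; adjusted p = 0.393 with an estimated correlation). Myh11 measured 6.32 ± 1.47 and 3.51 ± 0.695 FPKM, Des, which skeletal muscle shares, 48.4 ± 17.5 and 20.1 ± 6.75 FPKM, Rgs5 83.2 ± 14.7 and 69.7 ± 12.7 FPKM, and Acta2 45.2 ± 9.59 and 41.6 ± 6.49 FPKM. Of 10 cartilage genes limma called 0 over all genes and 0 adjusted over the list alone, with a median of 0.42 (camera adjusted p = 0.0163; adjusted p = 0.561 with an estimated correlation). Chad measured 168 ± 63.9 and 86.3 ± 12.7 FPKM, Cnmd 37.7 ± 8.11 and 29.6 ± 10.8 FPKM, and Sox9 10.7 ± 2.93 and 6.97 ± 0.720 FPKM. The cartilage list did not pass without CKO replicate 2 (camera adjusted p = 0.0981), FLOX replicate 2 (0.0618) or FLOX replicate 3 (0.127), nor without a filter (0.0789), and its median was 0.18 without CKO replicate 2 and 0.27 without FLOX replicate 2. The skeletal muscle list was higher by a median of 1.46 in these libraries, and with its mean as a covariate the smooth muscle list did not pass (camera adjusted p = 0.208).

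**Figure D3:**
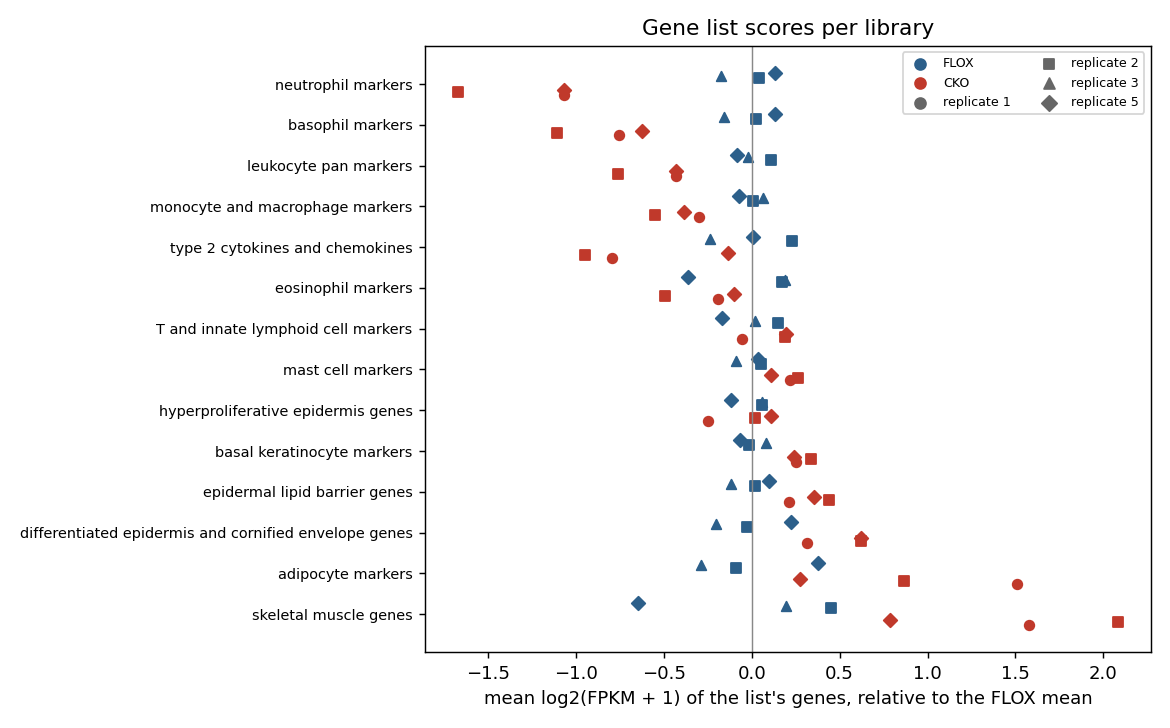
Mean log2(FPKM + 1) of the genes of 14 lists in each library, relative to the FLOX mean, with CKO in red, FLOX in blue and the replicate number as the marker shape. The skeletal muscle list lies at 0.79 to 2.08 in CKO and at -0.64 to 0.45 in FLOX libraries.

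Adhesion genes ranked lower and endothelial genes higher in CKO skin. Of 10 adhesion genes the integrin gene Itgam of myeloid cells fell (24.7 ± 2.60 against 39.9 ± 2.06 FPKM) and 9 did not pass; 2 were lower adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.0189; adjusted p = 0.341 with an estimated correlation). Itgb2, the partner chain of Itgam, measured 39.5 ± 1.24 and 51.9 ± 4.07 FPKM, the selectin ligand gene Selplg 51.1 ± 6.63 and 65.1 ± 7.46 FPKM, and the chemokine gene Ccl21a 166.7 ± 9.66 and 174.7 ± 16.4 FPKM. The list did not pass without CKO replicate 1 (camera adjusted p = 0.0509), and its median was -0.08 without CKO replicate 1 and -0.20 without CKO replicate 2. Of 11 endothelial genes limma called 0 over all genes and 0 adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.0376; adjusted p = 0.580 with an estimated correlation). Cldn5 measured 12.5 ± 3.44 and 7.79 ± 1.58 FPKM, Esam 14.6 ± 2.96 and 10.6 ± 1.57 FPKM, Pecam1 46.2 ± 8.68 and 42.7 ± 3.56 FPKM, and Lyve1 36.9 ± 6.90 and 30.6 ± 5.25 FPKM. That list did not pass without CKO replicate 1 (camera adjusted p = 0.0898), CKO replicate 2 (0.395), FLOX replicate 2 (0.0924) or FLOX replicate 3 (0.083), nor with array weights (0.0756) or without genes of other tissues (0.0526), and its median was 0.12 without CKO replicate 2 and 0.29 without CKO replicate 5. The muscle list was higher by a median of 1.46 in these libraries; with its mean as a covariate neither the adhesion list (0.0874) nor the endothelial list, whose direction turned (0.658), passed.

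Of the 16 SNARE and exocytosis genes, the family of the targeted gene and its partners, none passed over all genes, 1 was lower adjusted over the list alone, and the median was -0.10 (camera adjusted p = 0.00555; adjusted p = 0.341 with an estimated correlation). Snap23 measured 53.6 ± 6.04 and 75.1 ± 2.52 FPKM, Stxbp3 49.3 ± 1.14 and 58.5 ± 1.62 FPKM, Vamp8 268.7 ± 22.0 and 297.9 ± 18.4 FPKM, and Vamp3 75.9 ± 3.99 and 81.4 ± 4.47 FPKM. The list's median was -0.17 without FLOX replicate 5. Of the 13 unfolded protein response genes none passed over all genes, 1 was lower adjusted over the list alone, and the median was -0.11 (camera adjusted p = 0.0183; adjusted p = 0.341 with an estimated correlation). Xbp1 measured 92.6 ± 6.86 and 127 ± 10.6 FPKM, Pdia4 48.7 ± 2.48 and 65.8 ± 10.5 FPKM, Calr 266 ± 17.9 and 288 ± 29.5 FPKM, and Hspa5 195.4 ± 13.6 and 218.6 ± 13.7 FPKM. The list did not pass without CKO replicate 5 (camera adjusted p = 0.0619), with the filter at 5 FPKM (0.0753) or with quantile normalization (0.133), and its median was -0.07 without FLOX replicate 3 and -0.17 without FLOX replicate 5. Of the 20 cell cycle genes limma called 0 over all genes and 0 adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.00859; adjusted p = 0.561 with an estimated correlation). Mki67 measured 10.8 ± 1.55 and 14.3 ± 1.17 FPKM, Cdk1 8.16 ± 1.05 and 10.1 ± 1.35 FPKM, Pcna 116.5 ± 8.35 and 125 ± 13.9 FPKM, and Ube2c 23.6 ± 1.05 and 26.0 ± 1.74 FPKM. The list did not pass without CKO replicate 2 (camera adjusted p = 0.0604) or FLOX replicate 3 (0.228). Its median was -0.02 without FLOX replicate 3, -0.15 without CKO replicate 5 and -0.16 without FLOX replicate 5. The muscle list was higher by a median of 1.46 in the same CKO libraries, and with its mean as a covariate the cell cycle list did not pass (0.261).

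In total 13 lists were higher and 14 lower by camera with its preset correlation. With an estimated correlation 0 of the 27 lists passed, 2 of the 41 tested had an unadjusted p under 0.05, and the adjusted p of the 27 lay between 0.341 and 0.580. Fry's directional test passed 1 list, the adhesion genes (adjusted p = 0.000941), and its mixed test, which counts change either way, passed 25.

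Other immune lists did not pass camera. Alternatively activated macrophage genes had a median of -0.22 over 11 genes (camera adjusted p = 0.0509), with Chil3 at 159 ± 57.0 and 366 ± 117 FPKM and Retnla at 17.8 ± 13.6 and 11.9 ± 3.25 FPKM; 5 were lower adjusted over the list alone. The 13 arachidonate and leukotriene genes had a median of -0.31 (camera adjusted p = 0.0507), with 2 higher and 5 lower adjusted over the list alone. The 15 T and innate lymphoid cell genes had a median of 0.12 (camera adjusted p = 0.176) and the 18 interferon response genes a median of -0.03 (camera adjusted p = 0.181), each with 0 genes past limma over all genes and 0 adjusted over the list alone. The 13 dendritic and Langerhans cell genes had a median of 0.12 (camera adjusted p = 0.241), with 2 higher adjusted over the list alone. Of 7 vitamin D receptor targets Cd14 fell, 2 were lower adjusted over the list alone, and the median was -0.50 (camera adjusted p = 0.0697); Cyp24a1, which breaks down vitamin D, measured 342 ± 181 and 430.4 ± 99.5 FPKM. With 1 library left out, the vitamin D median ran from -0.84 (without CKO replicate 1) to -0.09 (without CKO replicate 2), the alternatively activated macrophage median from -0.38 (FLOX replicate 5) to -0.03 (CKO replicate 2), and the arachidonate median from -0.35 (FLOX replicate 2) to -0.14 (CKO replicate 2). The T and innate lymphoid median ran from -0.01 (FLOX replicate 5) to 0.25 (FLOX replicate 2) and the interferon median from -0.17 (CKO replicate 5) to 0.17 (CKO replicate 1), both with a change of sign, and the dendritic median from 0.03 (FLOX replicate 5) to 0.21 (FLOX replicate 2).

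Lists of other tissues and of housekeeping processes did not pass either. The median was 0.27 for 16 fibroblast and matrix genes (camera adjusted p = 0.131; 1 lower adjusted over the list alone), 0.12 for 10 heat shock genes (0.217; 3 higher adjusted over the list alone) and -0.34 for 5 hair follicle genes (0.129). It was 0.09 for 17 oxidative phosphorylation genes (0.276), -0.01 for 20 ribosomal protein genes (0.539) and -0.05 for 7 red blood cell genes (0.732). The 6 melanocyte genes had a median of 0.09 and a mean of 0.04, while camera ranked them lower (0.751). Hair follicle, oxidative phosphorylation, ribosomal, red blood cell and melanocyte lists had 0 genes past limma over all genes and 0 adjusted over the list alone. B and plasma cell genes (3 tested, median -0.14, 1 lower adjusted over the list alone) and histone genes (4 tested, median 0.09) were too few for camera, and mitochondrially encoded genes were not analysed here. When 1 library was left out, the fibroblast median ran from 0.10 (without CKO replicate 2) to 0.49 (without CKO replicate 5), the heat shock median from 0.08 (FLOX replicate 5) to 0.17 (FLOX replicate 2) and the hair follicle median from -0.55 (CKO replicate 5) to -0.24 (FLOX replicate 5). The red blood cell median (-0.44 without CKO replicate 2 to 0.27 without CKO replicate 5), the melanocyte median (-0.10 without FLOX replicate 3 to 0.29 without FLOX replicate 2) and the ribosomal median (-0.07 without CKO replicate 1 to 0.08 without CKO replicate 2) changed sign. Some lists that had not passed did so without 1 library. Without CKO replicate 5 the fibroblast (camera adjusted p = 0.000415), hyperproliferative (0.00942), interferon (0.00642), hair follicle (0.0154), alternatively activated macrophage (0.0309), vitamin D (0.0458) and arachidonate (0.0458) lists passed. Without FLOX replicate 5 the fibroblast (0.00618) and alternatively activated macrophage (0.00469) lists passed. The vitamin D list passed without CKO replicate 1 (0.0286), FLOX replicate 2 (0.0395) or FLOX replicate 3 (0.018). The T and innate lymphoid list passed without CKO replicate 1 (0.0251) or FLOX replicate 2 (0.0239), the dendritic list without FLOX replicate 2 (0.0136), the arachidonate list without CKO replicate 1 (0.0215), and the red blood cell list (0.0044) and the ribosomal list (0.0382) without CKO replicate 2.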

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

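The muscle covariate was chosen after the data were seen, and all other alternatives before. All called genes that could be tested kept their direction in every alternative. All of them kept an unadjusted p under 0.05, except 3 of 124 with the muscle covariate. The genes were called from these same libraries for large differences with small spread. Keeping direction and unadjusted p was thus likely whatever the cause, and is no independent support for the calls. In the main fit 120 genes shared a limma adjusted p of 0.047, close to the threshold, and whether this made the counts change was not tested. Against 46 higher and 78 lower genes, limma called 0 and 1 without a filter (2074 and 1308 at an unadjusted p under 0.05, more genes tested), 71 and 116 with the filter at 5 FPKM (fewer genes tested), 0 and 0 with quantile normalization (1286 and 1346 unadjusted, smallest adjusted p = 0.051), 15 and 17 without the trend, 4 and 6 with robust fitting, 104 and 170 with array weights, 73 and 148 without genes of other tissues, and 0 and 0 with the muscle covariate (388 and 240 unadjusted); the cause was not tested where none is named. The fit without genes of other tissues also rescaled each library, and the effects of these changes were not separated. Median-ratio scaling gave 42 and 116, and pseudocounts of 0.1 and 5 gave 47 and 73, and 41 and 73. Leaving out 1 library gave 0 to 225 higher and 0 to 192 lower genes, 0 of either without FLOX replicate 2 (1119 and 878 unadjusted) or FLOX replicate 3 (1436 and 963 unadjusted), and the most without CKO replicate 5. The list count of 27 was 17 with the muscle covariate, 0 with estimated correlation, 1 by directional fry (25 by mixed fry) and 22 to 32 without 1 library. The replicate numbers 2 and 5 occur in both groups, the labels tie no litter, batch or day to them, and the correlations of their deviations (0.13 and -0.11) lay within those of differently numbered pairs (-0.39 to 0.23), so they were not treated as pairs, which does not exclude that they are; with the replicate number as a block (1 residual degree of freedom) limma called 117 higher and 102 lower genes, 42 of the 124 among them. In that fit Klk8 (-0.0713) and Retnla (-0.19) and the interferon (adjusted p = 0.417), fibroblast (0.933) and hyperproliferative (0.933) lists had the opposite sign, the mast cell (0.12), eosinophil (0.0899), endothelial (0.117), cell cycle (0.332) and unfolded protein (0.054) lists did not pass, and the T cell (0.0307), vitamin D (0.0002) and arachidonate (0.00661) lists did. Other reversals were of genes and lists that had not passed, apart from the endothelial and skeletal muscle lists. The mean of the skeletal muscle list is the covariate of the muscle fit, so that list's difference was removed there by construction. Mylpf is a member of the skeletal muscle list. Quantile normalization reversed Ccl21a (0.0072) and the ribosomal list (0.851), array weights the ribosomal list (0.94), and the filter at 5 FPKM the melanocyte list (0.739). The muscle covariate reversed Tslp (0.80), Pecam1 (-0.20), Lyve1 (-0.11), Mylpf (-0.0573), Acta2 (-0.0871), Retnla (-0.48), Krt6a (0.12) and Cyp24a1 (0.72), and the T cell (0.832), interferon (0.878), endothelial (0.658), hair follicle (0.563), skeletal muscle (0.789), vitamin D (0.153), oxidative phosphorylation (0.563) and ribosomal (0.0927) lists. Leaving out 1 library gave log2 fold changes of -0.21 to 0.72 for Retnla, -0.0326 to 0.24 for Pecam1, -0.0497 to 0.24 for Acta2, -0.19 to 0.0167 for Krt6a, -0.84 to 0.0561 for Cyp24a1, -0.0059 to 0.24 for Krt16, -0.0393 to 0.31 for Klk8 and -0.21 to 0.0126 for Lyz2, and adjusted p of 0.00642 to 0.37 for the interferon, 0.0382 to 0.648 for the ribosomal, 0.0044 to 0.97 for the red blood cell and 0.152 to 0.909 for the melanocyte list, each with a change of sign. Over all alternatives, named genes kept their sign but fell short of the threshold in 252 cases and passed it anew in 50, and lists in 97 and 33. Lists that had not passed did so without a filter (alternatively activated macrophage 0.0399, vitamin D 0.0315, arachidonate 0.0399), with the filter at 5 FPKM (arachidonate 0.0321), quantile normalization (fibroblast 0.028, heat shock 0.0334, oxidative phosphorylation 0.0129), array weights (alternatively activated macrophage 0.0462), and without genes of other tissues (alternatively activated macrophage 0.025, vitamin D 0.0437, arachidonate 0.0282). Count-based normalizations, count filters and count tests from the plan were not run because the table holds FPKM. Depth is unknown and limits what can be said of genes near 1 FPKM.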

Other observations

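The genes and tests in this part were chosen after the results were seen, except the splits of the libraries. Single genes outside the lists were picked by hand from the 78 lower and 46 higher ones, and were not tested as groups. Of the lower ones, the chemokine receptor gene Ccr1 measured 61.5 ± 15.2 FPKM in CKO and 131 ± 17.1 FPKM in FLOX skin, the inhibitory receptor gene Siglece 5.89 ± 1.75 and 14.2 ± 1.48 FPKM, and Cd300lf 19.7 ± 5.62 and 45.4 ± 1.00 FPKM. The adaptor gene Lcp2 fell by 1.05 on the log2 scale, the adaptor gene Pik3ap1 by 0.80, and the Src-family kinase gene Fgr by 0.77. Srgn, the core protein of granule proteoglycans, measured 453 ± 132 and 1066 ± 58.9 FPKM, and Tnfsf14, which encodes the cytokine LIGHT, 11.9 ± 2.13 and 25.3 ± 0.720 FPKM. Among 406 groups of genes that share a symbol stem, 14 passed camera and 0 passed with an estimated correlation (adjusted p = 0.987 for each of the 14). The 8 colony-stimulating factor and receptor genes (Csf) had negative fold changes in all 8, with a median of -0.60, and -0.64 and -0.60 under the median-ratio and quantile scalings.

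Of the higher genes, Sostdc1, which encodes a secreted inhibitor of BMP and Wnt signals, measured 9.01 ± 1.31 FPKM in CKO and 4.40 ± 0.874 FPKM in FLOX skin, the Wnt inhibitor gene Apcdd1 12.2 ± 1.35 and 7.23 ± 0.477 FPKM, the BMP antagonist gene Nbl1 91.6 ± 11.6 and 56.5 ± 4.36 FPKM, and the hedgehog target gene Gli1 1.94 ± 0.08 and 0.893 ± 0.145 FPKM. The acyl-CoA synthetase gene Acsl1 measured 33.0 ± 2.11 and 21.5 ± 0.890 FPKM, the glycerol-phosphate acyltransferase gene Gpam 8.43 ± 0.763 and 5.50 ± 0.223 FPKM, and the monooxygenase gene Fmo1 23.1 ± 2.82 and 11.5 ± 0.687 FPKM. All 9 tested Skint genes had positive fold changes, with a median of 0.69 (camera adjusted p = 0.000250; adjusted p = 0.987 with an estimated correlation), and medians of 0.67 and 0.58 under the median-ratio and quantile scalings; of these Skint9 passed. Mill1, an MHC class I-like gene of skin, rose from 5.23 ± 0.770 to 12.5 ± 3.00 FPKM.

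The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave 46 higher and 78 lower genes and the highest of the others gave 0 and 0, so 1 split of 10 reached the real count in each direction. For lists past camera the real split gave 27 and the highest other 24, again with 1 split of 10. With 10 splits the share cannot be under 0.05.

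Basophil and neutrophil genes were lower in CKO skin, and dilution of leukocyte RNA by added muscle and fat RNA should have lowered lymphoid genes as much. The T and innate lymphoid list instead differed by 0.11. That lies above the basophil list by 0.94 and above the neutrophil list by 1.38 (error bounds 0.714 and 0.847). The lymphoid values argue against dilution as the whole cause only if lymphoid cells were as frequent in both groups, which was not measured. All else equal, added muscle and fat RNA should also have lowered genes of other skin cells by as much. The basal keratinocyte list instead lay at 0.24 to 0.34 in CKO and -0.07 to 0.08 in FLOX libraries. The median log2 fold change of all tested genes was 0.03. Those results argue against such dilution as the whole cause of the basophil (-0.83) and neutrophil (-1.27) differences. Fewer basophils in the skin may account for the lower basophil genes, but Mcpt8 and Prss34 fell by different amounts without a pseudocount (difference -0.65, SE 0.22), and Prss34 lies too near 0 FPKM to decide between fewer cells and less Mcpt8 per cell. Mice with only the transgene used for such deletions and intact Vamp7 were represented by 0 libraries here, so an effect of the transgene on basophils cannot be told apart from the loss of VAMP7. The loss of VAMP7 itself stays open as a hypothesis.

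Skeletal muscle genes were higher in CKO skin and may reflect different amounts of the muscle under the skin in the samples. The genes moved as a block within groups, with an estimated inter-gene correlation of 0.929. Lists that did not pass also had high values, 0.87 for red blood cell and 0.81 for ribosomal protein genes. The correlation therefore cannot decide whether muscle content differed. The fit with the muscle list's mean as a covariate cannot decide whether muscle content is the whole cause of the other called genes. In it the median fold change of the 123 called genes outside the muscle list kept 84.1% of its size. The median went from 0.84 (median SE 0.12) to 0.70 (median SE 0.21). The covariate's slope rests on spread within groups, and the genes were called from these data for small spread relative to their difference. Small slopes were thus likely whatever the cause, and the muscle list's means did not overlap between the groups. All 123 kept their direction and 120 had an unadjusted p under 0.05, but limma called 0 genes; the folds shrank, the SE grew and 3 residual degrees of freedom remained, and their shares in the loss of calls were not separated. Mcpt8 had a log2 fold change of -2.22 (SE 0.22) without the covariate and -1.64 (SE 0.32) with it.

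Differentiated epidermis genes were higher in CKO skin, and a larger epidermal share of the RNA could raise them. In that case, all else equal, keratins of the inflamed epidermis should have been higher by as much. The mean difference of Krt6a, Krt6b, Krt16 and Krt17 was 0.0059, and that of the differentiated list exceeded it by 0.52 (SE 0.19). Inflammatory genes such as Il1b and S100a9 were lower in CKO skin, and lower inflammation could offset a larger share in these keratins. The comparison therefore cannot decide on epidermal share. The differentiated list exceeded the basal keratinocyte list by 0.24 (SE 0.19), within the spread, so a larger epidermal share stays open. The knockout genotype itself stays open as well, untested.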
